A study of Rattus norvegicus with 12 samples.

How the data were processed

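RNA from marrow cell cultures of male Wistar-Hannover rats was measured on Illumina rat expression arrays. Per the labels, marrow of the tibia and femur was cultured to osteoblasts or to osteoclasts, RNA of 3 to 4 animals was pooled for each of 3 treatments, and each of the 6 resulting pools was arrayed in duplicate, which gives 12 arrays on 1 chip. The duplicates share an RNA pool and are technical, so each treatment in a culture type is represented by n = 1 pool. Per the labels, biotinylated cRNA was prepared with a MessageAmp kit. The scanner software and its settings are not given in the sources used here.

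The deposited table of 22523 probes gives an intensity and a detection p-value for each array, per the file headers. Between 26.8% and 30.4% of the deposited intensity values lay below 0, which shows that a background had already been subtracted, by software not named in the sources used here. The deposited detection p-value compares a probe with the negative controls of its own array and moves in steps of 1 over 825. The authors' series matrix holds, on the linear scale, a straight-line rescaling of the same intensity values, with a slope of 0.731 to 1.42 and a shift of its own for each array and r = 1 between the matrix and the scanner values. Its column medians ran from 13.8 to 19.1, and its 75th percentiles were 146 to 151 on the osteoblast arrays and 123 to 125 on the osteoclast arrays. The rule by which the authors set slope and shift stays unknown, while scale and direction follow from this comparison. No column belonged to a sample outside the series.

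The choices of tests, gene lists, rule for naming genes and most alternative settings were made before the data were examined. That plan set neqc of limma as the main normalization, with a fallback for signals already corrected for background. Because they were, the fallback was used: normexp by limma's own fit with an offset of 50, quantile normalization over the 12 arrays, and log2. The offset understates the folds of dim genes. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

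Probes were named by the symbol in the file, matched to the current symbols and synonyms of the RefSeq gene table. A symbol was updated where it was a synonym of a single gene and was either a placeholder, backed by the synonyms in the file, or the older symbol of a listed gene with no other probe. Of the probes, 10281 had a current symbol, 2469 were given an updated one, 9656 kept the symbol in the file and 117 had none and were counted by probe. An older symbol that the reference gives to several genes, such as Pthr1, was left as in the file and entered no list under another name. This gave 21645 genes. A gene with several probes (818 genes) was represented by its brightest probe over all arrays. Among the named genes, a detected probe that was not used gave a smaller difference for Ifit1 after SCI in osteoclast cultures (-0.92 against -1.65), and the other probes of Col11a1, Myh11 and Nr4a3 were not detected. Study genes with no matched probe (Sfrp1, Acp5, Nfatc1, Itgb3 and Dcstamp) were not analysed here, although the older symbol Tm7sf4 was read in the osteoclast list.

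A treatment comparison within a culture type has a single pool on each side and therefore no test. A gene was counted as higher or lower by a size rule: at least 2-fold between pool means, both arrays of the higher pool above both arrays of the lower, and a detection p of at most 0.01 on both arrays of at least 1 of the pools. The error beside a difference is the standard error over duplicate arrays and covers array error only. It says nothing of the spread between animals or cultures. The precision is limited by the number of arrays and pools. Where a gene was not detected on any array of the dimmer pool, the fold is given as "at least N-fold": the brighter pool's mean against, per array of the dimmer pool, the higher of the lowest detected level and the probe's own level. Where some arrays of the dimmer side detected the gene, only the other arrays were set in this way, and the same was done between culture types.

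Gene lists were described by the median difference of their detected members and by that median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list is called apart when the percentile lies under 2.5 or over 97.5. The percentile describes these pools and is not a test. The 23 lists covered osteoblast markers, extracellular matrix and collagen processing, osteoclast markers, monocyte and macrophage markers, adipocyte genes, Wnt ligands, receptors and targets, secreted Wnt antagonists, the BMP and TGF-beta pathway, osteoclastogenic cytokines, interferon response, inflammatory chemokines and acute phase, cell cycle, smooth muscle and myofibroblast genes, cartilage genes, B cell and MHC class II genes, T and NK cell genes, granulocyte and mast cell genes, erythroid genes, endothelial genes, immediate early and mechanoresponsive genes, hypoxia and glycolysis genes, oxidative phosphorylation, and heat shock and amino acid stress response.

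Osteoclast cultures were compared with osteoblast cultures over the 6 pool means, 3 on each side, with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg), calling genes at an adjusted p under 0.05 and at least 2-fold. Pools of different treatments serve as replicates there, so their spread includes the treatments. Lists were tested with camera at the preset correlation of 0.01 and again with an estimated correlation.

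Genes were named by a fixed rule: the 10 largest differences in each direction for each comparison of SCI with sham and of SCI+FES with SCI, up to 4 members of each list with the largest differences, 22 genes of the study question, the 10 highest and 10 lowest genes between culture types, and the 10 largest of the genes that passed the size rule in both treatment comparisons or with opposite signs between culture types. Placeholder symbols were passed over. Genes outside the rule are marked in the text as chosen after their values were seen.

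The size rule, the list percentile and the limma gene calls were tested on simulated data. For SCI against sham in osteoblast cultures (8275 genes), the size rule called 0% of 50 genes set to 1.5-fold, 100% of those at 2.5-, 3- and 4-fold, and 0 unchanged genes. These simulated arrays held array error only and no spread between pools. The rates therefore say nothing of false calls that arise from animals or cultures. With independent random differences for the same genes, 4 of 200 unshifted lists of 20 random genes (2%) were called apart. Of lists shifted by 0.5 on the log2 scale, 200 of 200 were called apart. Genes of the lists used here can move together, so the 2% need not hold for them. For osteoclast against osteoblast cultures (8906 genes), limma recovered 32%, 78%, 86% and 96% of 50 genes each at 2-, 3-, 4- and 8-fold, with 3 false calls.

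The alternatives tried were log2 of the signal plus 16 without background correction, neqc with an offset of 50, scaling to a common median in place of quantile normalization, separate normalization of the culture types, the authors' matrix values, a detection p of at most 0.05, no detection filter, size rules of 1.5- and 3-fold, all probes counted separately, each array left out in turn, limma over the arrays with and without a replicate block, SCI arrays split between comparisons, and, between culture types, treatment as a term, each pool left out, and a trended robust prior. After the data were seen, neqc with an offset of 16 and a common median over all probes were added.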

Results

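Gene expression was measured in cells grown from the bone marrow of sham-operated rats, rats with spinal cord injury (SCI) and rats with SCI whose paralysed hindlimb muscle was made to contract by functional electrical stimulation (SCI+FES). Marrow cultures were differentiated to osteoblasts, which form bone, or to osteoclasts, which resorb it. Per the labels, stimulators were implanted 14 weeks after SCI and stimulation started in week 16, for 60 minutes a day on 7 days, in contractions of 2 s followed by 18 s of rest, at 40 Hz and 1.5 V. Sham marrow was taken 12 to 14 weeks after surgery. For SCI animals with sham stimulation the labels give collection at week 17. They give the implant at week 14 for the SCI pools too, and not for the sham pools. Differences between SCI and sham may therefore also reflect the implant and the time after surgery. Each of the 6 groups was 1 RNA pool of 3 to 4 animals, hybridised to 2 arrays as technical duplicates, so the treatment comparisons are values with no test and no replicate check between animals. The probes detected per array ranged from 33.7% to 38.3%. Duplicate arrays correlated at r = 0.996 to 0.997 across genes, which are not independent replicates, with an array SD of 0.10 on the log2 scale, and 0 genes differed 2-fold between duplicates. Differences are given on the log2 scale ± the standard error over duplicate arrays, which covers array error only.

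To investigate whether the cultures had the character of their cell type, the 3 osteoclast pools were compared with the 3 osteoblast pools. The labels give culture day 10 for the osteoblast pools, day 3 for the sham and SCI+FES osteoclast pools and no day for the SCI osteoclast pool. Culture time therefore differs along with the culture type. Osteoclast cultures had higher levels of Mmp9, a matrix-degrading protease of resorbing osteoclasts (6.36 ± 0.25, adjusted p = 2.63e-05 by limma), of Atp6v0d2, a subunit of the proton pump that acidifies bone (4.34 ± 0.18, adjusted p = 2.87e-05), and of Ctsk, the main collagen-degrading protease of osteoclasts (2.57 ± 0.26, adjusted p = 0.000787). Metallothionein Mt3 showed the largest increase (7.67 ± 0.29, at least 187-fold). Stfa2, the globin Hba-a2, Napsa, Gal, S100a8, Lcn2 and Ccr1 were also among the 10 highest named genes. Osteoblast cultures had higher levels of the contractile genes Actg2 (-7.90 ± 0.18, osteoclast minus osteoblast, at least 171-fold) and Tagln (-6.67 ± 0.22, at least 78.2-fold), of the chemokine Cxcl12 (-6.69 ± 0.13, at least 88.8-fold), and of the matrix genes Dcn (-6.69, at least 94.8-fold), Col3a1 (-6.52, at least 74.8-fold), Sparc (-6.39), Thbs2 (-6.30, at least 52.2-fold) and Lum (-6.29). Fstl1 and the gap junction gene Gja1 were also among the 10 lowest. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that blocks RANKL, was lower in osteoclast cultures (-4.78 ± 0.30, at least 14.9-fold, adjusted p = 9.89e-05), as was Alpl, the alkaline phosphatase of mineralising cells (-3.35 ± 0.61, at least 8.76-fold, adjusted p = 0.00826). Bglap, which encodes osteocalcin, did not pass (-1.44 ± 0.66, at least 1.99-fold, adjusted p = 0.145 by limma), with an SD of 1.48 between the osteoblast pools.

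Of 8906 genes tested, 434 were higher and 590 lower in osteoclast cultures by limma at the adjusted p and size thresholds, and 2648 passed the adjusted p at any size. The number higher was 693 with log2 of the signal plus 16 and 673 with neqc at an offset of 16. Among osteoclast markers, 17 of 20 tested members rose, 17 also when adjusted over the list alone, and the median was 2.23 (camera adjusted p = 2.46e-13, and adjusted p = 0.159 with an estimated correlation). Among matrix and collagen processing genes, 24 of 29 fell, 24 adjusted over the list alone (median -3.35, camera adjusted p = 7.79e-18, and adjusted p = 0.159 with an estimated correlation). Smooth muscle genes fell in 8 of 9 (8 adjusted over the list alone, median -3.13, camera adjusted p = 5.00e-09, and adjusted p = 0.170 with an estimated correlation), and osteoblast markers in 8 of 16 (9 adjusted over the list alone, median -1.30, camera adjusted p = 1.58e-06, and adjusted p = 0.437 with an estimated correlation). Oxidative phosphorylation had a median of 0.56 with 1 of 24 members called (camera adjusted p = 1.26e-06, and adjusted p = 0.159 with an estimated correlation), and the Wnt list a median of -0.60 with 4 of 14 lower (5 adjusted over the list alone, camera adjusted p = 1.59e-05, and adjusted p = 0.159 with an estimated correlation). The interferon list had a median of 0.98 with 6 of 28 higher (2 adjusted over the list alone, camera adjusted p = 0.000145, and adjusted p = 0.569 with an estimated correlation). Adipocyte genes (median 0.58), the BMP and TGF-beta list (median -0.42) and the cell cycle list (median -0.48) had camera adjusted p of 0.0264, 0.00525 and 0.0088, and 0.212, 0.510 and 0.771 with an estimated correlation. Macrophage markers did not separate the culture types, with 4 higher and 5 lower of 20 (median 0.33, camera adjusted p = 0.281, and adjusted p = 0.771 with an estimated correlation). Of these 20, 19 were detected in the sham or SCI osteoblast pool, so osteoblast cultures expressed them as well. None of the 22 lists tested held its call with an estimated correlation, the lowest adjusted p being 0.159. For osteoclastogenic cytokines, immediate early genes and the heat shock list, medians of 0.13, 0.02 and 0.23 stood against a camera direction of lower, without a call.

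To investigate how osteoblast cultures differ after SCI, the SCI osteoblast pool was compared with the sham osteoblast pool. Several markers of mature osteoblasts were higher after SCI. Panx3, a channel gene of osteoblasts and chondrocytes, showed the largest difference (4.34 ± 0.07, 20.3-fold), and Ifitm5, a bone-restricted membrane protein, was 9.22-fold higher (3.20 ± 0.02). The genes for bone sialoprotein, Ibsp (2.02 ± 0.07, 4.06-fold), osteocalcin, Bglap (1.97 ± 0.22, 3.91-fold), and alkaline phosphatase, Alpl (1.19 ± 0.14, 2.28-fold), and the osteocyte matrix gene Dmp1 (2.18 ± 0.10, at least 3.78-fold) were higher too. Of 16 detected osteoblast markers 4 were higher and 0 lower, and the list median of 0.71 stood apart from random lists. Spp1 (-0.02), Tnfrsf11b (0.02), Wnt5a (-0.14) and Lrp5 (0.05) differed little, and Dkk1, a secreted Wnt antagonist, did not pass the size rule (0.90 ± 0.09, at least 1.17-fold).

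**Figure D1:**
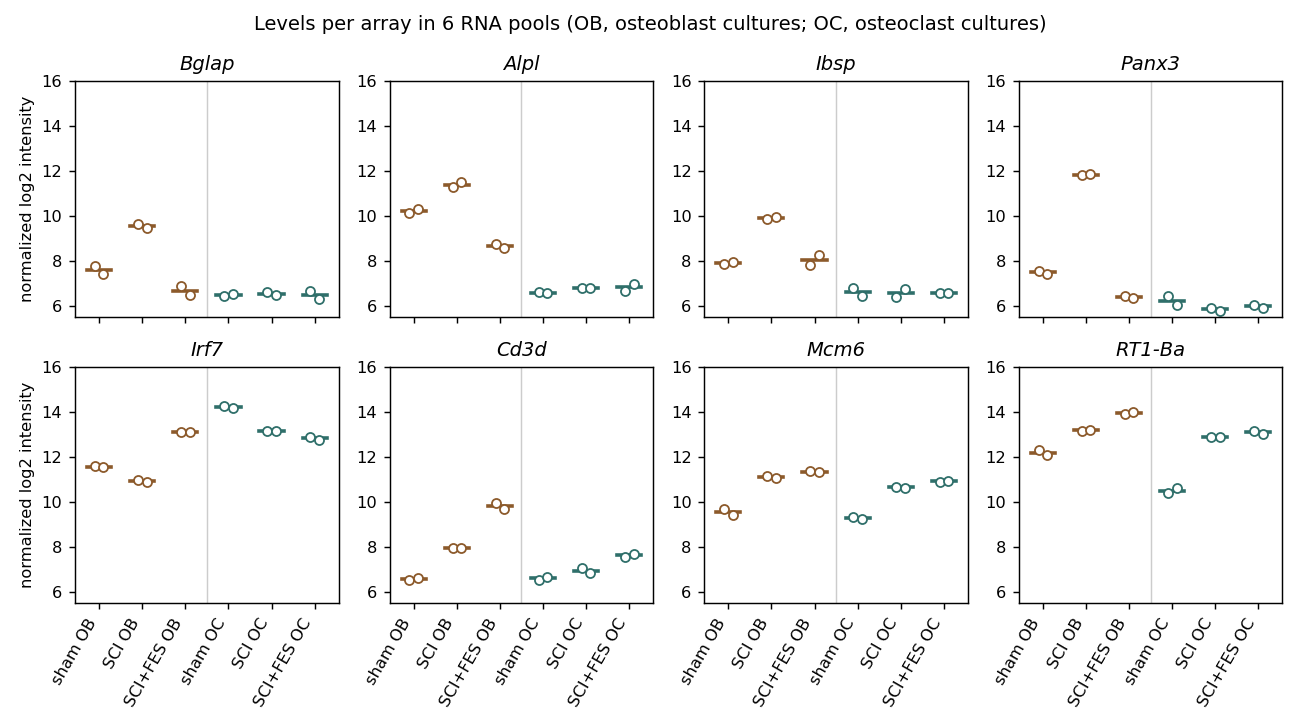
Normalized log2 intensity (y axis) of 8 genes on each array of the 6 RNA pools (x axis), with points for the 2 technical duplicate arrays, bars for their mean, and OB and OC for osteoblast and osteoclast cultures. Bglap, Alpl, Ibsp and Panx3 are highest in the SCI osteoblast pool, Cd3d is highest in the SCI+FES osteoblast pool, and RT1-Ba is 2.38 higher in the SCI than in the sham osteoclast pool.

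Among the 23 lists, the cell cycle list had the most members higher. Of 26 cell cycle genes 14 were higher and 0 lower (median 1.08), with Rrm2, a subunit of the enzyme that makes deoxyribonucleotides (1.76 ± 0.15), the mitotic genes Ube2c (1.60 ± 0.12) and Ccna2 (1.60 ± 0.04), and the replication helicase gene Mcm6 (1.55 ± 0.14). The BMP and TGF-beta list had a median of 0.33, with the BMP target genes Id1 (1.67 ± 0.05) and Id3 (1.07 ± 0.09) higher. Immediate early genes had a median of 0.36, with Fos (1.59 ± 0.01), Junb (1.22 ± 0.05), Ier3 (1.20 ± 0.08) and Ccn1 (1.06 ± 0.05) higher among 18.

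Some inflammatory genes were higher as well. The cytokine gene Il1b was 7.92-fold higher (2.99 ± 0.11), and the chemokine genes Ccl17 (3.27 ± 0.08, at least 5.77-fold), Cxcl10 (1.79 ± 0.06), Ccl2 (1.61 ± 0.13) and Cxcl9 (1.56 ± 0.11) were higher. Medians were 0.35 for 17 inflammatory chemokine and acute phase genes (2 higher, 1 lower) and 0.33 for 12 osteoclastogenic cytokines (Il1b and Ccl2 higher). The interferon median was 0.16 (4 higher and 2 lower of 25), but -0.05 under a common median over all probes. That scaling put the median of the detected genes at -0.22, and the list was still apart as higher there. Some T cell and mast cell genes were higher too. T and NK cell genes had a median of 0.65 with Cd3d (1.37 ± 0.04, at least 2.25-fold) and Cd3g (1.30 ± 0.13, at least 2.35-fold) higher among 10, and the mast cell genes Cpa3 (1.51 ± 0.02), Hdc (1.14 ± 0.03, at least 1.97-fold) and Fcer1a (1.02 ± 0.02, at least 1.53-fold) were higher among 5 granulocyte and mast cell genes (median 1.02). MHC class II genes had a median of 0.68 with none of 5 past the size rule, and 19 macrophage markers were not apart (median -0.04). Ch25h, which makes 25-hydroxycholesterol, the prostacyclin synthase gene Ptgis, the retinoic acid hydroxylase gene Cyp26b1, Mamdc2 and the mitochondrial ribosomal gene Mrpl17 completed the 10 largest positive differences (2.18 to 2.90).

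The genes that were lower after SCI in osteoblast cultures included those of the amino acid stress response. The stress list had a median of -0.48 and 4 of 14 members lower: Trib3 (-2.32 ± 0.19, at least 3.54-fold), Phgdh, of serine synthesis (-1.83 ± 0.15), Ddit3 (-1.77 ± 0.12) and Asns, asparagine synthetase (-1.52 ± 0.10). The transcription factor gene Atf5 was also lower (-2.36 ± 0.10), along with Itm2a (-2.76 ± 0.15, 6.75-fold), Clu, an extracellular chaperone (-2.22 ± 0.11), the muscle gene Mylpf (-1.91 ± 0.06, at least 2.71-fold), Aox1, Egfl6 and Akr1b10. The osteoclast list was lower (median -0.24, 1 of 17, Mmp9 -1.01 ± 0.04), with Ctsk at -0.67. The matrix list had a median of -0.23 with Postn lower among 29 (-1.13 ± 0.11, and -0.94 in the authors' matrix values), but a median of 0.05 in the authors' matrix values. The smooth muscle median was 0.29, with Des higher among 9 (1.15 ± 0.08). Adipocyte (-0.17), Wnt (0.05, Tcf7 higher), secreted Wnt antagonist (-0.03), endothelial (0.16), hypoxia (0.01, Ddit4 lower) and oxidative phosphorylation (0.02) medians were not apart, and 1 cartilage and 0 erythroid genes were detected.

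In all, 166 genes were higher and 117 lower among 8275 detected. Counts were 323 and 251 with log2 of the signal plus 16 and 310 and 227 with neqc at an offset of 16. Under a common median over all probes, which puts the median of the detected genes at -0.22, counts were 95 and 214. There, Alpl (0.88), Junb, Ier3, Ccn1, Des, Id3, Tcf7 and Ccl4 no longer reached 2-fold. Without the detection filter the medians of osteoclastogenic cytokines (0.05), T and NK cell genes (0.07) and granulocyte and mast cell genes (0.04) were not apart, the matrix list lost its place under 3 of 9 settings, the interferon list under 4, and the smooth muscle list under neqc with an offset of 16.

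**Figure D2:**
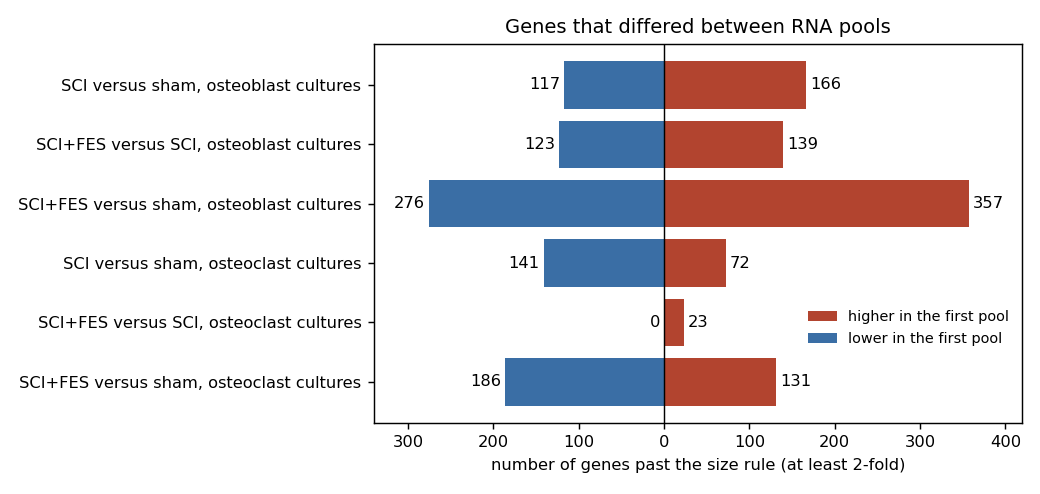
Number of genes past the size rule (x axis, higher to the right and lower to the left) in each comparison of RNA pools (y axis). In osteoblast cultures 166 genes were higher and 117 lower after SCI, and in osteoclast cultures 23 were higher and 0 lower in the SCI+FES pool than in the SCI pool.

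To investigate whether osteoblast cultures differ with muscle stimulation, the SCI+FES osteoblast pool was compared with the SCI osteoblast pool. Osteoblast markers were lower in the stimulated pool. Panx3 was at least 32.8-fold lower (-5.45 ± 0.04), Ifitm5 at least 15.1-fold lower (-4.25 ± 0.02), Bglap at least 6.69-fold lower (-2.89 ± 0.21) and Alpl 6.61-fold lower (-2.72 ± 0.14). Of 16 detected osteoblast markers 9 were lower and 0 higher, with a median of -1.35; Ibsp (-1.88 ± 0.23, 3.69-fold), Dmp1 (-2.29 ± 0.14, at least 3.74-fold) and Smpd3, a sphingomyelinase needed for mineralisation (-2.36 ± 0.13), were among them. Tnfrsf11b was lower (-1.09 ± 0.04, 2.12-fold), and Tnfsf11, which encodes RANKL, the cytokine that drives osteoclast formation, was detected in the stimulated pool only and did not pass the size rule (0.76 ± 0.16, at least 1.26-fold). Spp1 (0.04), Wnt5a (-0.08), Lrp5 (-0.02), Dkk1 (-0.80, at least 1.16-fold) and Ctsk (-0.43) did not pass the size rule, and Runx2, Sp7 and Axin2 were not detected in any pool.

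Some other mesenchymal genes were lower too. The matrix list had a median of -0.45 with 6 of 29 lower, including the small proteoglycan genes Aspn (-2.86 ± 0.07, 7.28-fold) and Ogn (-2.50 ± 0.07), Col6a3 (-1.68 ± 0.08) and the crosslinking enzyme gene Loxl2 (-1.56 ± 0.05). Col11a1 was the cartilage gene detected (-2.09 ± 0.12). Smooth muscle genes had a median of -0.67, with Smtn (-1.76 ± 0.13), Myh11 (-1.05 ± 0.16) and Myl9 (-1.02 ± 0.07) lower among 9. The BMP and TGF-beta list (-0.25), secreted Wnt antagonists (-0.65, 3 detected) and endothelial genes (-0.59, 4 detected) stood apart as lower with no member past the size rule. Pthr1 (-2.96 ± 0.08), Aard, Mamdc2, Penk, which encodes proenkephalin, and Ptgis were also among the 10 largest negative differences.

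Immune genes were higher in the stimulated osteoblast pool. Of 27 interferon response genes 13 were higher and 0 lower (median 0.99), with Irf7, a transcription factor that amplifies interferon production (2.17 ± 0.05, 4.49-fold), the antiviral genes Mx1 (2.15 ± 0.09) and Oasl (2.15 ± 0.04), and Cxcl11 (2.14 ± 0.13). Of 13 T and NK cell genes 7 were higher (median 1.15), including the T cell receptor complex genes Cd3g (1.96 ± 0.01), Cd3d (1.88 ± 0.13) and Cd247 (1.62 ± 0.27) and Cd8a (1.96 ± 0.04), and the T cell activation genes Il2ra (2.42 ± 0.08, 5.37-fold) and Tnfrsf4 (2.22 ± 0.21) were higher. Osteoclastogenic cytokines had a median of 0.82 with 6 of 13 higher and Tnfrsf11b lower. In order of size the higher ones were Il1a (2.34 ± 0.07), Ptgs2, the inducible prostaglandin synthase (1.75 ± 0.04), Il1rn, Il1b (1.13 ± 0.04), Ccl2 and Il18. Il1rn encodes the IL-1 receptor antagonist, so the higher members did not all act in 1 direction. Inflammatory genes had a median of 0.72 with Ccl20 (1.73 ± 0.21), Cxcl6 (1.50 ± 0.13, at least 2.31-fold), Sod2 (1.41 ± 0.05) and Ccl4 (1.19 ± 0.02) higher among 16. Macrophage markers had a median of 0.33, with Cd163 (1.47 ± 0.09) and Cd14 (1.16 ± 0.07) higher among 19. Plac8 (2.92 ± 0.06, 7.57-fold), the B cell chemokine gene Cxcl13 (2.39 ± 0.05) and Ubd, a ubiquitin-like modifier induced by interferon gamma (2.29 ± 0.13), were among the largest differences.

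Cell cycle (0.36), hypoxia and glycolysis (0.31), MHC class II (0.37), granulocyte and mast cell (0.37, Prg2 -1.10 ± 0.07) and stress response (0.22, Phgdh higher and Hspb1 lower) medians were apart as higher in the stimulated osteoblast pool. Osteoclast markers (0.02), adipocyte genes (-0.10, Acsl1 1.22 ± 0.19), the Wnt list (-0.07), immediate early genes (-0.01, Klf2 -1.35 ± 0.03) and oxidative phosphorylation (-0.09) were not, although Car2, a carbonic anhydrase of osteoclasts, was higher (1.99 ± 0.02, 3.97-fold). In all, 139 genes were higher and 123 lower among 8183. Counts were 255 and 268 with log2 of the signal plus 16 and 242 and 258 with neqc at an offset of 16. Under a common median over all probes Tnfrsf11b (-0.89), Myh11, Myl9, Hspb1 and Prg2 no longer reached 2-fold, and without the detection filter the MHC class II and granulocyte medians (0.02 and 0.05) were not apart. The granulocyte median was not apart with log2 of the signal plus 16 (0.52) and at a detection p of at most 0.05 (0.18) either.

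**Figure D3:**
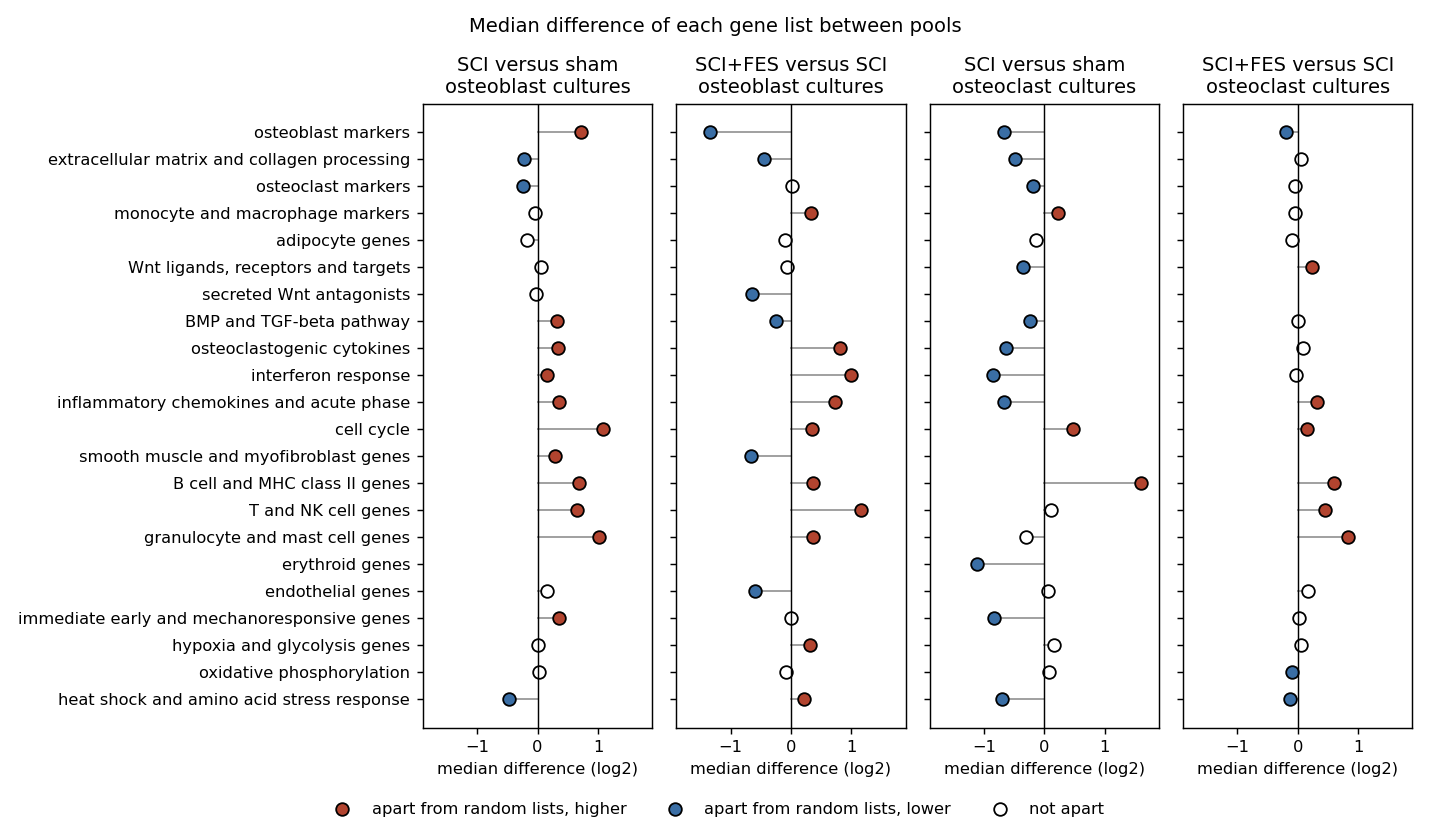
Median log2 difference (x axis) of the detected members of each gene list (y axis) in 4 comparisons of RNA pools, filled where the median was apart from random lists. Osteoblast markers lie at 0.71 for SCI against sham and at -1.35 for SCI+FES against SCI in osteoblast cultures. Under a common median over all probes signs turn for interferon after SCI in osteoblast cultures (-0.05, median of the detected genes -0.22). For SCI+FES against SCI in osteoclast cultures they turn for Wnt (-0.22), inflammatory (-0.09) and cell cycle genes (-0.22, median of the detected genes -0.35). Of these lists, only Wnt is not apart as higher under that scaling. In the authors' matrix values signs turn for matrix genes after SCI in osteoblast cultures (0.05) and oxidative phosphorylation for SCI+FES against SCI in osteoclast cultures (0.02).

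To investigate whether the stimulated osteoblast pool lay closer to sham, both differences were set side by side. Of the 166 genes higher after SCI, 27 were lower again by the size rule in the SCI+FES pool, 21 were higher still, and 125 remained past the rule against sham. Of the 117 genes lower after SCI, 16 were higher again, 5 were lower still and 76 remained past the rule. The genes that were higher after SCI and then lower included Panx3, Ifitm5, Ptgis, Mamdc2, Dmp1, Bglap, Cyp26b1, Ibsp and Alpl. Ubd, Il1b, Cxcl10, Cd3d and Cd3g were higher in both steps. Genes past the rule in opposite directions numbered 43 and in the same direction 26, where independent lists would share 4.25 and 4.30. Those expected numbers leave out the shared SCI pool, which by itself adds opposite pairs. With log2 of the signal plus 16 there were 83 opposite and 60 alike. Across 8534 genes, which are not independent replicates, the correlation of both differences was -0.00756 (covariance -0.00121), against a simulated -0.50 for unchanged pools that share the SCI pool. Without the SCI osteoblast array 2 the correlation was -0.0809, and with the SCI arrays split between the differences it was 0.0346, against a simulated -0.478 for that split.

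Against sham, the SCI+FES osteoblast pool had 357 genes higher and 276 lower of 8423. These numbers were 593 and 555 with log2 of the signal plus 16, and 564 and 522 with neqc at an offset of 16. Il1b was 17.3-fold higher (4.11 ± 0.11), Cxcl10 13.7-fold (3.78 ± 0.15) and Cd3g at least 9.12-fold (3.26 ± 0.13). Of 26 cell cycle genes 20 were higher, as were 9 of 13 T and NK cell genes (1.54), 9 of 17 inflammatory genes (1.13, with Vcam1 lower) and 13 of 27 interferon genes (0.92). Osteoblast markers had a median of -0.77 with 4 of 13 lower, including Smpd3 (-1.73 ± 0.13), Alpl (-1.54 ± 0.12) and Col1a1 (-1.19 ± 0.06), while Ibsp (0.14 ± 0.23) and Bglap (-0.93 ± 0.28, at least 1.71-fold) did not pass the size rule. The matrix list had a median of -0.57 with 8 of 29 lower, led by Ogn (-3.48 ± 0.05, 11.2-fold) and Aspn (-3.24 ± 0.08). Ctsk (-1.10 ± 0.06) and Tnfrsf11b (-1.07 ± 0.04) were lower. In the authors' matrix values Ctsk (-0.73), Tnfrsf11b (-0.86) and Col1a1 (-0.88) no longer reached 2-fold, and without the detection filter the median of the osteoblast list (-0.12) was not apart.

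To investigate how osteoclast cultures differ after SCI, the SCI osteoclast pool was compared with the sham osteoclast pool. MHC class II genes, which present antigen to T cells, were higher after SCI. All 5 detected MHC class II genes were higher (median 1.61), led by RT1-Ba (2.38 ± 0.12, 5.22-fold), the invariant chain gene Cd74 (1.67 ± 0.04) and RT1-Db1 (1.61 ± 0.10). Macrophage markers had a median of 0.22 with 3 of 19 higher, which were Adgre1, encoding the F4/80 antigen (1.99 ± 0.14, 3.96-fold), and the complement genes C1qb (1.18 ± 0.08) and C1qc (1.07 ± 0.09). The scavenger receptor gene Msr2 (2.42 ± 0.05), Mcemp1 (2.18 ± 0.08), the neuropeptide gene Gal (2.10 ± 0.18), the kinase gene Eef2k (2.10 ± 0.02), Lgals1, which encodes galectin-1 (1.99 ± 0.03), the lectin gene Mgl1 (1.86 ± 0.05), Cd72 (1.81 ± 0.08) and Mrpl17 (2.79 ± 0.03, at least 6.13-fold) completed the largest positive differences. Cell cycle genes had a median of 0.47, with the helicase genes Mcm6 (1.36 ± 0.04) and Mcm2 (1.10 ± 0.07) higher among 23.

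Interferon and inflammatory genes were lower in the SCI osteoclast pool. Of 28 interferon genes 12 were lower and 0 higher (median -0.85), including Ifit3, Cxcl11 (-1.94 ± 0.12), Ifit1 (-1.65 ± 0.06) and Cxcl10 (-1.61 ± 0.12). The inflammatory list had a median of -0.66 with 4 of 13 lower, the chemokine genes Ccl4 (-2.85 ± 0.05, 7.22-fold), Cxcl1 (-2.83 ± 0.04), Cxcl2 (-2.82 ± 0.04) and Ccl3 (-2.03 ± 0.02). Osteoclastogenic cytokines had a median of -0.64, with Ptgs2 (-2.14 ± 0.05) and Il1a (-1.16 ± 0.07) lower among 11, and immediate early genes a median of -0.83, with Atf3 (-1.53 ± 0.06), Dusp1 (-1.33 ± 0.07), Fos (-1.19 ± 0.06) and Nr4a3 (-1.10 ± 0.04, at least 1.81-fold) lower among 17. The stress list had a median of -0.70, with the heme oxygenase gene Hmox1 (-1.49 ± 0.08) and Trib3 (-1.29 ± 0.11) lower among 14.

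The osteoclast list was apart as lower, under all 9 settings, with a median of -0.20 and 2 of 20 members lower: Jdp2 (-1.51 ± 0.06) and Traf6, an adaptor of RANK signalling (-1.03 ± 0.10). Ctsk (0.15), Mmp9 (0.06 ± 0.11), Tnfrsf11a, which encodes RANK (-0.14 ± 0.17), and Calcr, the calcitonin receptor gene (-0.31 ± 0.10, at least 1.14-fold), did not pass the size rule. Markers of other cells were lower in part. Fcnb, a ficolin of myeloid cells, was the lowest (-3.17 ± 0.09), and the defensin genes Defa (-2.62 ± 0.11, at least 4.66-fold), Np4 (-2.43 ± 0.12, at least 2.66-fold) and RatNP-3b (-2.36 ± 0.14, at least 2.36-fold) were lower, while 4 granulocyte and mast cell genes had a median of -0.31 that was not apart. The globin genes Hba-a2 (-1.19 ± 0.07) and Hbb (-1.12 ± 0.02) were lower among 3 erythroid genes (median -1.12). The matrix list had a median of -0.48 with Lum (-1.92 ± 0.02), Postn and Col3a1 lower and Fn1 higher (1.69 ± 0.06) among 18, and of 6 osteoblast markers (median -0.67) Col1a2 was lower (-2.26 ± 0.14), and Kazald1 (1.72 ± 0.27, at least 2.80-fold) and Smpd3 higher. The BMP and TGF-beta list had a median of -0.23, with Grem1, a BMP antagonist (-1.78 ± 0.06, at least 2.23-fold), Smad7, an inhibitor of TGF-beta signalling (-1.37 ± 0.05, at least 2.35-fold), and Id2 (-1.02 ± 0.10) lower among 15. The antiviral helicase-like gene Ddx60 was lower too (-2.45 ± 0.08).

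Wnt genes had a median of -0.36 with none of 6 past the size rule, while adipocyte (-0.14), T and NK cell (0.11), endothelial (0.07), hypoxia (0.16) and oxidative phosphorylation (0.08) medians were not apart. Of secreted Wnt antagonists and smooth muscle genes 1 each was detected, and 0 cartilage genes. In all, 72 genes were higher and 141 lower among 7658. Counts were 195 and 308 with log2 of the signal plus 16, 189 and 295 with neqc at an offset of 16, and 212 lower under a common median over all probes. Without the detection filter the erythroid median was 0.03 and the osteoblast median -0.11, neither apart, and the Wnt median was 0.01 at a detection p of at most 0.05. Id2 (-0.87 in the authors' matrix values), C1qc (0.99 under a common median over all probes) and Nr4a3 (-0.99 with the culture types normalized separately) no longer reached 2-fold.

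To investigate whether osteoclast cultures differ with stimulation, the SCI+FES osteoclast pool was compared with the SCI osteoclast pool. Only 23 of 7438 genes passed the size rule, all higher, and 3 of them belong to the granulocyte and mast cell list. Prg2, the eosinophil major basic protein gene, was 7.30-fold higher (2.87 ± 0.02), and the neutrophil genes S100a8 (2.18 ± 0.04, 4.54-fold), Pglyrp1 (2.12 ± 0.08) and Mmp8 (1.72 ± 0.19, at least 3.27-fold) were higher, as were the myeloid gene Retnlg (2.21 ± 0.03), the decoy receptor gene Il1r2 (2.06 ± 0.07), Stfa2 (1.73 ± 0.03), the eosinophil ribonuclease gene Ear11 (1.54 ± 0.13, at least 2.27-fold), Ifitm6 (1.47 ± 0.09, at least 2.53-fold) and the mast cell protease gene Mcpt10 (1.44 ± 0.07, at least 1.97-fold). The granulocyte and mast cell list had a median of 0.84 with 3 of 7 higher. Only 2 of these 7, Prg2 and S100a8, were detected on both arrays of the SCI pool. The others entered through the SCI+FES pool, which raises the median. Over the settings the median was as low as 0.27, apart under all 9. Ctsk (0.01 ± 0.03), Mmp9 (0.05 ± 0.08), Spp1 (0.07 ± 0.10), Sost (0.20 ± 0.14) and Tnfrsf11a (0.18 ± 0.07) did not pass the size rule, and 19 osteoclast markers had a median of -0.04 that was not apart. Under a common median over all probes, which puts the median of the detected genes at -0.35, the counts were 13 higher and 3 lower. With log2 of the signal plus 16 they were 64 and 16.

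With no member past the size rule, MHC class II (0.61), T and NK cell (0.46), inflammatory (0.32, but -0.09 under a common median over all probes), Wnt (0.23, but -0.22 under that scaling) and cell cycle (0.15, but -0.22 under that scaling) medians were apart as higher in the stimulated osteoclast pool. That scaling put the median of the detected genes at -0.35, and the inflammatory and cell cycle lists were still apart as higher there. Oxidative phosphorylation (-0.09, but 0.02 in the authors' matrix values), the stress list (-0.12) and 4 osteoblast markers (-0.20, but 0.10 without the detection filter) were apart as lower. Interferon (-0.02), macrophage (-0.05), matrix (0.06), adipocyte (-0.10), BMP and TGF-beta (0.01), osteoclastogenic cytokine (0.09), endothelial (0.16), immediate early (0.02) and hypoxia (0.06) medians were not apart. The endothelial median was not apart under only 3 of 9 settings, so its place is not settled. Under 3 of 9 settings the Wnt median was not apart, and under 4 the osteoblast median was not apart as lower.

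No gene passed the size rule in opposite directions after SCI and after stimulation in osteoclast cultures, where independent lists would share 0.297. However, 11 did with log2 of the signal plus 16, 8 with neqc at an offset of 16 and 2 with neqc at an offset of 50. Ubd, Il1r2, Stfa2 and 2 genes with placeholder names were higher in both steps, where independent lists would share 0.177. Under a common median over all probes, Ubd (0.88) no longer reached 2-fold between SCI+FES and SCI. Of the 72 genes higher after SCI, 66 remained past the rule against sham in the SCI+FES pool, and of the 141 lower, 126 did. The correlation across 7771 genes, which are not independent replicates, was 0.0825 (covariance 0.00665). The simulated -0.50 assumes independent pools of equal spread, which the SDs of 0.404 for SCI minus sham and 0.201 for SCI+FES minus SCI do not match, so it gives no reference here. The correlation was 0.00227 and -0.0252 without SCI osteoclast array 1 or 2, and 0.163 with the SCI arrays split. Against sham, the SCI+FES osteoclast pool had 131 genes higher and 186 lower of 7640: MHC class II genes had a median of 2.00 with RT1-Ba (2.59 ± 0.13), RT1-Db1 (2.43 ± 0.16) and Cd74 (2.21 ± 0.11) higher, cell cycle genes a median of 0.63 with 6 of 24 higher, and interferon genes a median of -0.99 with 14 of 28 lower and Cxcl9 higher. S100a8 (2.70 ± 0.03) and Prg2 (2.25 ± 0.03) were higher. Under a common median over all probes, which puts the median of the detected genes at -0.40, the counts against sham were 49 and 685. There, Mcm2, Mcm3 (0.85) and Mcm7 (0.76) no longer reached 2-fold. With log2 of the signal plus 16 the counts against sham were 324 and 403, and with neqc at an offset of 16 they were 316 and 384.

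To investigate whether both culture types differed alike, differences were compared between them. After SCI, 36 genes passed the size rule in the same direction in both, 17 higher and 19 lower, where independent lists would share 2.37. With log2 of the signal plus 16 there were 112, and with neqc at an offset of 16 there were 108. Mrpl17 (2.90, at least 7.32-fold, in osteoblast and 2.79 in osteoclast cultures), Ubd (2.15 and 1.46, at least 3.37-fold and 1.94-fold), Eef2k (1.57 and 2.10), Mcm6 (1.55 and 1.36) and Mcm2 (1.24 and 1.10) were higher in both, and Trib3 (-2.32 and -1.29) and Ddx60 (-1.33 and -2.45) lower in both. Single genes were opposite: Ccl4 (1.07 and -2.85), Cxcl10 (1.79 and -1.61), Cxcl11 (1.40 and -1.94), Fos (1.59 and -1.19), Zfp36, which promotes the decay of cytokine mRNA (1.41 and -1.16), and a gene with a placeholder name were higher in osteoblast and lower in osteoclast cultures, 6 in all where independent lists would share 2.82 (13 and 12 under those settings). Ccl4 fell short of 2-fold in osteoblast cultures under a common median over all probes (0.75). The correlation of the SCI differences across 7211 genes was 0.368. For SCI+FES against SCI it was 0.0906 across 7080 genes, 0.0571 without array 1 of the SCI+FES osteoblast pool, and -0.00562 under a common median over all probes. In that comparison, 5 genes were higher in both culture types, among them Ubd, Il1r2, Retnlg and Ltb, the last chosen after its values were seen. The number was 18 with log2 of the signal plus 16, 17 and 8 with neqc at offsets of 16 and 50, and 3 under a common median over all probes. Under that common median, Ubd (0.88) and Ltb (0.84) did not reach 2-fold in osteoclast cultures. With scaling to a common median, Retnlg (0.94) did not reach 2-fold in osteoblast cultures. Prg2 and Ear11 were lower in osteoblast and higher in osteoclast cultures. Independent lists would share 0.217 and 0.0734. Genes are not independent replicates, and the differences between culture types were not tested.

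**Figure D4:**
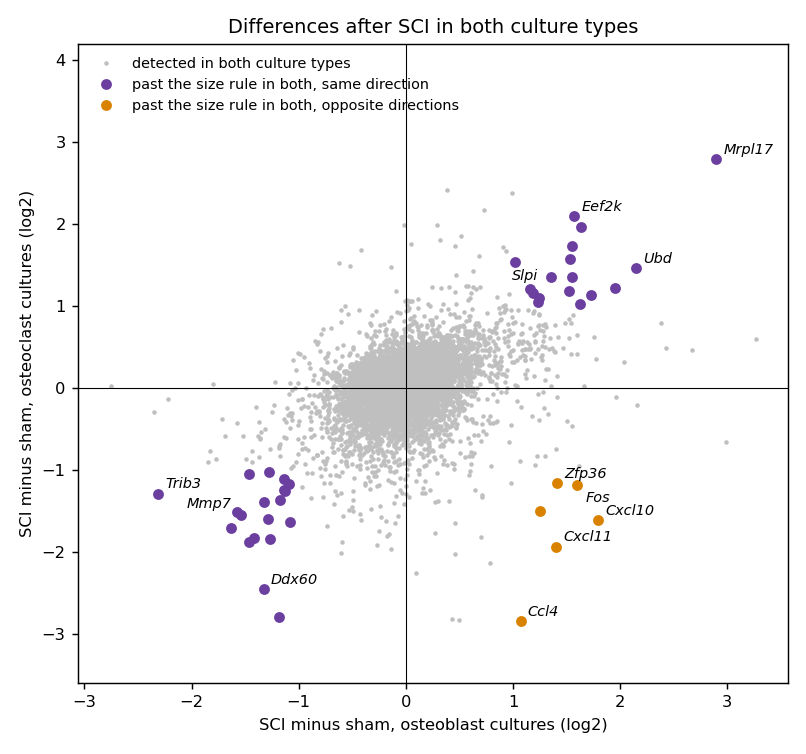
SCI minus sham on the log2 scale in osteoblast cultures (x axis) and osteoclast cultures (y axis) for the 7211 genes detected in both, each point a gene. The 36 genes past the size rule in the same direction, such as Mrpl17 and Trib3, and the 6 in opposite directions, such as Ccl4 and Cxcl10, are coloured.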

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

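The genes of this part stood out because they passed the size rule in opposite directions in osteoblast and osteoclast cultures, placeholder names left out. The lists stood out because their medians were apart from random lists in opposite directions, each with the same sign for either array number. Genes and lists were picked out by these rules from the values, and none of the differences between culture types was tested. Each is the difference in osteoclast cultures minus the difference in osteoblast cultures, from 1 pool per group, on the log2 scale.

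After SCI, 5 named genes were higher in osteoblast and lower in osteoclast cultures. The gap was -3.92 for Ccl4, -3.40 for Cxcl10 and -3.34 for Cxcl11, whose products recruit T cells and monocytes, -2.78 for Fos, a subunit of the AP-1 transcription factor, and -2.58 for Zfp36. Among gene lists it was -1.38 for osteoblast markers (0.71 in osteoblast and -0.67 in osteoclast cultures), -1.19 for immediate early genes (0.36 and -0.83), -1.01 for interferon response (0.16 and -0.85), -1.01 for inflammatory chemokines (0.35 and -0.66), -0.97 for osteoclastogenic cytokines (0.33 and -0.64) and -0.56 for the BMP and TGF-beta pathway (0.33 and -0.23). The osteoblast medians cover different members, 16 in osteoblast and 6 in osteoclast cultures. Of these 6, Kazald1 and Smpd3 were higher and Col1a2 lower, and without the detection filter the osteoclast median was -0.11 and not apart. The interferon median in osteoblast cultures was -0.05 under a common median over all probes. The median of the detected genes was -0.22 there, and the list was still apart as higher. With scaling to a common median, in the authors' matrix values, at a detection p of at most 0.05 and without the filter it was not apart. Under those settings the list was therefore not apart in opposite directions.

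Between SCI+FES and SCI, eosinophil genes were lower in osteoblast and higher in osteoclast cultures, with a gap of 3.96 for Prg2 and 2.71 for Ear11, and the stress list had the opposite pattern (-0.34, from 0.22 and -0.12). Prg2 did not reach 2-fold in osteoblast cultures under a common median over all probes (-0.94). The compared pools also differed in their labels. The original IDs carry the number 1302 for both SCI+FES pools and for the SCI osteoclast pool (with an added L for SCI+FES and R for SCI in osteoclast cultures), 1314 for the SCI osteoblast pool and 1372 for both sham pools, and the meaning of these numbers is not given.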

How the results depend on the processing

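Of 81 list medians in the 4 main comparisons 53 were apart, 40 of them under all 9 settings, and 9 of these 53 changed sign under at least 1 setting. Sign changes of medians that were not apart are not listed. Of those not apart, the endothelial list for SCI+FES against SCI in osteoclast cultures stayed so under 3 of 9 settings. The median of the osteoblast list stayed apart under all settings for SCI against sham and for SCI+FES against SCI in osteoblast cultures. Of 299 named calls all were kept with log2 of the signal plus 16 and with neqc at either offset, 295 with separate normalization of the culture types, 289 in the authors' matrix values, 284 with scaling to a common median and 271 with a common median over all probes, and 0 changed direction. The settings with 16 in place of 50 shrink folds less, so calls could hardly be lost there. Signal over background limits dim genes: with the offset of 50, folds near the background are too small.

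Gene counts are given as higher and lower for SCI against sham, SCI+FES against SCI and SCI+FES against sham, first in osteoblast and then in osteoclast cultures. A 1.5-fold rule, which by construction admits more genes, gave 475 and 417, 366 and 415, 829 and 794, then 323 and 476, 79 and 5, 498 and 618. A 3-fold rule gave 34 and 19, 35 and 32, 113 and 68, then 19 and 39, 10 and 0, 36 and 48. Log2 of the signal plus 16, which shrinks dim genes less, gave 323 and 251, 255 and 268, 593 and 555, then 195 and 308, 64 and 16, 324 and 403. The added neqc with an offset of 16 gave 310 and 227, 242 and 258, 564 and 522, then 189 and 295, 63 and 10, 316 and 384. The added common median over all probes gave 95 and 214 for SCI against sham in osteoblast cultures, and in osteoclast cultures 212 lower for SCI against sham, 13 and 3 for SCI+FES against SCI, and 49 and 685 for SCI+FES against sham. It put the median of the detected genes at -0.22, 0.08 and -0.15 in osteoblast cultures and at -0.07, -0.35 and -0.40 in osteoclast cultures. Between culture types, 693 genes were higher in osteoclast cultures with log2 of the signal plus 16 and 673 with neqc at an offset of 16, against 434.

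Genes past the rule in opposite and in the same direction after SCI and with FES numbered 83 and 60 in osteoblast and 11 and 8 in osteoclast cultures with log2 of the signal plus 16, 75 and 58 and then 8 and 8 with neqc at an offset of 16, and 2 opposite in osteoclast cultures with neqc at an offset of 50. Genes opposite and alike in the culture types after SCI numbered 13 and 112 with log2 of the signal plus 16, and 12 and 108 with neqc at an offset of 16. For SCI+FES against SCI they numbered 4 and 18, and 4 and 17, with 8 alike under neqc at an offset of 50 and 3 alike under a common median over all probes.

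The correlation of SCI minus sham with SCI+FES minus SCI in osteoblast cultures was -0.0899 without the detection filter, 0.0346 with the SCI arrays split, and -0.0809 to -0.00540 when leaving out an array. In osteoclast cultures it was 0.0515 with log2 of the signal plus 16, 0.0493 with neqc at an offset of 16, 0.0409 with scaling to a common median, 0.0242 with a common median over all probes, 0.0508 at a detection p of at most 0.05, -0.103 without the filter, 0.163 with the SCI arrays split, and -0.0252 to 0.0844 when leaving out an array. The correlation of SCI minus sham between culture types was 0.387 with log2 of the signal plus 16 and with neqc at an offset of 16, 0.390 with scaling to a common median, 0.403 in the authors' matrix values, 0.355 at a detection p of at most 0.05, 0.256 without the filter, and 0.355 to 0.368 when leaving out an array. For SCI+FES minus SCI it was 0.0550 with scaling to a common median, -0.00562 with a common median over all probes, 0.0420 without the filter, and 0.0571 to 0.118 when leaving out an array. The cause of these shifts was not tested.

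Among medians that were apart, those that changed sign were, in osteoblast cultures after SCI, the interferon list (-0.0543 under a common median over all probes and -0.0454 without the detection filter) and the matrix list (0.0456 in the authors' matrix values). In osteoclast cultures after SCI they were the Wnt list (0.0134 at a detection p of at most 0.05) and the erythroid list (0.0264 without the filter). For SCI+FES against SCI in osteoclast cultures they were the Wnt (-0.22), inflammatory (-0.0886) and cell cycle (-0.22) lists under a common median over all probes, oxidative phosphorylation (0.0159 in the authors' matrix values) and osteoblast markers (0.10 without the filter). For SCI+FES against sham in osteoclast cultures they were the erythroid list (0.0942 without the filter) and the hypoxia list (-0.13 under a common median over all probes). The common median over all probes lowered the detected genes as a whole. Their median was -0.22 for SCI against sham in osteoblast cultures. In osteoclast cultures it was -0.35 for SCI+FES against SCI and -0.40 for SCI+FES against sham. Under that scaling the interferon, inflammatory, cell cycle and hypoxia lists were still apart as higher, and the Wnt list was not apart. The cause of the other sign changes was not tested.

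The array numbers 1 and 2 paired the samples weakly at most. Of 15 pairs of groups 4 had a correlation over 0.1 between deviations, over 6358 genes, from -0.0799 to 0.157. A weak part shared by array number is not excluded. A replicate block in limma over the arrays left all counts unchanged, with 166 higher and 117 lower for SCI against sham in osteoblast cultures, 139 and 123 for SCI+FES against SCI, 357 and 276 for SCI+FES against sham, and 72 and 141, 23 and 0, and 131 and 186 in osteoclast cultures. Array error was small (SD 0.10), so differences of at least 2-fold passed with or without the block. The unchanged counts therefore cannot show whether array number matters. At any size, the block gave 3336 genes against 3281 for SCI against sham in osteoblast cultures, counted against array error alone.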

Other observations

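Platelet and other blood genes outside the naming rule, chosen after their values were seen, were also higher in the SCI+FES than in the SCI osteoclast pool. The platelet receptor gene Gp1bb (1.33) and the platelet chemokine gene Ppbp (1.14) were higher, after lower values in the SCI pool than in the sham pool (-0.80 and -0.71), and lay 0.53 and 0.43 above sham. The chitinase-like gene Chi3l1 (1.33), the haptoglobin gene Hp (1.16) and the secreted phospholipase gene Pla2g2a (1.05) were higher too, as was the lymphocyte gene Ltb (1.17, at least 2.22-fold).

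Single genes among the 36 that shared their direction in both culture types after SCI are added here. The replication genes Pole2 (1.53 in osteoblast and 1.18 in osteoclast cultures) and Rpa2 (1.23 and 1.05) and the protease inhibitor gene Slpi (1.36 and 1.36) were higher, and the amino acid transporter gene Slc7a5 (-1.42 and -1.84), the matrix protease gene Mmp7 (-1.54 and -1.56), the lipid antigen-presenting gene Cd1d1 (-1.57 and -1.51) and the stress gene Nupr1 (-1.32 and -1.39) were lower. These were chosen after their values were seen.

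Most tests in this part were chosen after the result was seen. The predictions on normalization and on the processing of the sham arrays were written first.

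Osteoblast markers were lower in the SCI+FES than in the SCI osteoblast pool. Fewer osteoblast-lineage cells, with every blood cell type raised alike, might lower them. The T and NK cell median exceeded the macrophage median by 0.82 (permutation p = 0.00336), which speaks only to an equal rise. Fewer osteoblast-lineage cells with unequal changes in the other cells stay possible. A loss of stromal cells of every kind might do the same. Osteoblast markers lay 0.90 below matrix genes (permutation p = 0.00808). However, matrix genes (median -0.45, 4 of 29 above 0) and smooth muscle genes (median -0.67, 0 of 9 above 0) were lower too. An uneven loss of stromal cells stays possible. Both permutations treat genes of 1 pool per side as independent and were chosen after the result was seen, so neither settles the source. Normalization moved the median no nearer to 0 than -0.95. With 1 pool per group, animals and cultures are not separable from stimulation, although all osteoblast pools carry day 10 in their labels.

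The 36 genes shifted alike in both culture types after SCI may reflect a change of the marrow, the sham arrays, or sequence variants between animals that alter probe binding. The count was never under 36 over the processing settings. All settings use the same sham arrays, so this count cannot tell whether those arrays are the source. The 75th percentile of the deposited intensity was 191 and 204 on the sham and 126 and 151 on the SCI osteoblast arrays. On the osteoclast arrays it was 147 and 143 for sham and 109 and 127 for SCI. A variant under single probes could not be judged, because only 1 shared gene had another detected probe. Both comparisons use sham pools with the same number in their IDs. Sham marrow was collected at 12 to 14 weeks, while the labels give week 17 for SCI animals with sham stimulation. The labels also give the SCI pools, and not the sham pools, an implant at week 14. Animal, implant, time and the sham arrays therefore remain possible sources.

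Only higher genes in the SCI+FES osteoclast pool might come from more granulocyte RNA. Of the granulocyte and mast cell list 3 of 7 members were among the 23 of 7438 genes (two-sided exact Fisher p = 8.97e-07). This value restates the genes that prompted it and treats genes of 1 pool per side as independent, so the source stays open. S100a8 stood at 9.29, 9.81 and 11.99 and Prg2 at 8.06, 7.44 and 10.31 in the sham, SCI and SCI+FES pools. Camp stood at 7.44, 6.79 and 7.35, and of the osteoclast pools only the SCI+FES pool had Hdc and Ngp detected on both arrays. The neutrophil genes S100a9 and Ltf were not detected on any osteoclast array, so their probes do not speak for or against this source. Of 20 list genes the sham osteoclast pool also expressed 4 and the SCI pool 2, and 0 were in another list. The small number of genes might instead reflect marrow of the same animals behind both pools, since their differences had an SD 0.50 times that between the osteoblast pools (0.201 and 0.402), which does not separate shared animals from a weak response. The IDs of these pools carry the same number, followed by R for SCI and L for SCI+FES, letters whose meaning is not given. The label of the SCI osteoclast pool carries no culture day, where the other osteoclast pools carry day 3.

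Between culture types, the split of the 6 pools by culture gave 1024 genes and the highest other of 10 splits 0. With 3 pools against 3, only 1 of 10 splits is the real one, so a share under 0.05 cannot occur.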
